A study of Arabidopsis thaliana with 24 samples.

How the data were processed

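The series measures poly-A RNA in leaves of 4-week-old Arabidopsis thaliana Col-0 by paired-end Illumina sequencing. Per the labels, 24 libraries form 8 groups of 3: β-ionone for 3 h and for 24 h, an acetone mock for each of these times, a further 24 h mock, Botrytis cinerea infection for 24 h, and β-ionone followed by infection for 24 h and for 48 h. The β-ionone spray held 50 µM of the compound, with acetone and a detergent as carriers. The labels give all 8 groups the same carriers, 1% acetone and 0.05% detergent. The name acetone mock serves here only to tell that mock from the further 24 h mock, which held acetone as well. The labels do not settle whether the libraries were stranded, so expression from overlapping or antisense genes, and among near-identical relatives such as the CAB, SAUR, GST and defensin genes, is less certain. Nothing in the labels beyond the sample names says that replicates came from separate plants, pools or batches, so p-values measure the spread between samples only. Some sample codes give the 24 h mock and the 24 h β-ionone group as 0 h; the time in the titles was used.

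The authors' processing notes name HISAT2 and StringTie; their versions, the genome build, the read counter and the test are not given in the sources used here. The 5 deposited tables each compare a treated group with its mock and hold only genes with the authors' adjusted p below 0.05. Per the file headers each holds raw read counts per gene and FPKM values computed by the authors, a log2 fold change on the authors' normalized counts, and p-values with adjusted p-values. The deposited normalized signal columns are the authors' counts divided by 1 factor per library, as the values show. The number of genes the authors tested was recovered from the relation of p-value to adjusted p-value: 18871, 23536, 22013, 21839 and 22586. Gene symbols were joined from a table of the TAIR10.1 assembly; all 31177 listed identifiers matched, covering 15882 distinct genes of 38312 annotated. No coordinates are printed.

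Library totals implied by counts and FPKM ran from 44.0 to 66.6 (in 1e6 reads) over the 24 libraries: 46.9–50.3 for β-ionone at 24 h, 45.2–47.9 at 3 h, 44.5–45.3 for the acetone mock, 47.0–49.2 for the 24 h mock, 44.0–66.6 for infection alone, 46.4–56.4 and 45.7–49.1 for the combination at 24 h and 48 h. A gene with a group total below 3 counts cannot be told from absence at this depth; for such a group the change is printed as at least the fold reached with 3 counts in that group. This floor covers counting error only. Between libraries, an SD of 3 values is the error given.

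The 2 acetone mock groups hold identical counts and were counted as 1, leaving 21 distinct libraries. The main count of each comparison is the authors' own list. Because unlisted genes are not in the tables, refits are checks on genes already chosen by the authors' test and are not independent of it. Listed counts were refitted with edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma 3.58.1 (on log2(FPKM + 1)) in R 4.3.3, with each p-value adjusted by Benjamini and Hochberg over the number of genes the authors tested. Standard errors of log2 changes are from DESeq2. Differences between treated groups (combination against infection alone, 48 h against 24 h of the combination, β-ionone at 24 h against 3 h) were tested with edgeR over genes listed in both tables, adjusted over the genes tested. The 24 h mock was compared with the acetone mock and with β-ionone at 24 h over genes listed in the 24 h β-ionone table and an infection table, scaled by library totals. The slope of their changes was set beside the slope found when 1 acetone mock library takes the place of the 24 h mock and another serves as control. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 did the rest.

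Genes are named by a rule. In each comparison it takes the 6 largest rises and 6 largest falls. These have an adjusted p below 0.05, groups that do not overlap, a symbol and a mean of at least 100 normalized counts. The 16 sentinel genes are named as well, though not for every table that lists them. Up to 3 members of each list with the smallest adjusted p are added, of which some are left out. Genes named for the difference between the combination and infection alone were picked by the same rule in a fit chosen after the values were seen. 18 pathway lists and 5 cell-type lists, 475 distinct genes, were written before the data were examined, as were the grouping of samples, the comparisons and the first set of alternatives. A list of 16 genes induced by darkness or lack of sugar was added afterwards. Listed members higher and lower were compared with the other listed genes by Fisher's exact test, adjusted within each table (108 tests over the 5 tables). With p-values adjusted over the list alone, 114 of 120 pairs of list and table (counting the added list) held the same number of members past 0.05. The other 6 held at least 2 (photosynthesis at 3 h), 12, 7, 3 and 0 (ethylene, heat, flavonoid and epidermis at 24 h of β-ionone) and 3 members (aliphatic glucosinolates at 48 h). These are minimum counts, since p-values of unlisted members are not in the tables.

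Alternatives tried were an FDR of 0.01, a 2-fold minimum, a mean of at least 10 counts, no filter, the 3 tools, TMM factors, library totals, replicate number as a block, the compared groups alone and each library left out. The edgeR fits were tested on simulated data of the same sizes with 200 changed genes: of 4-fold changes they recovered 99% (β-ionone at 3 h), 86% (24 h), 43% (infection alone), 55% and 32% (combination at 24 h and 48 h), and of 2-fold changes 63%, 64%, 3%, 1% and 0%. Gene-set tests that need all genes were left out because only chosen genes are in the tables. Overlaps of tables with a common control were compared with simulated tables that share their controls, because 3 controls cannot be divided into sets of at least 2. Isoforms and fungal transcripts are not analysed here.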

Results

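Leaves of 4-week-old Arabidopsis were compared with mock-treated leaves 3 h and 24 h into treatment with the volatile apocarotenoid β-ionone and 24 h after infection with the necrotroph Botrytis cinerea. Leaves given β-ionone first were compared 24 h and 48 h after infection. Each group holds 3 libraries. The deposited tables list only genes with the authors' adjusted p below 0.05: 3315, 12617, 5209, 4275 and 5761 genes for the 5 comparisons in that order. Gene values are means ± SD of normalized counts (n = 3) as treated against control. Fold changes, given bare in brackets as log2, and adjusted p-values are the authors', and standard errors (SE) come from a DESeq2 refit of the listed genes. A gene outside a table did not pass there or was not tested, and its size of change is unknown. PR1 (AT2G14610), BGL2 (AT3G57260), PDF1.2a (AT5G44420), PAD3 (AT3G26830), CYP71A13 (AT2G30770) and LOX2 (AT3G45140), common markers of these pathways, are in none of the 5. Other markers were listed as higher at 3 h of β-ionone: PR5 (AT1G75040, log2 3.11, authors' adjusted p 0.0293), VSP2 (AT5G24770, log2 1.80, authors' adjusted p 0.00327) and GSTU24 (AT1G17170, log2 2.68, authors' adjusted p 0.00235).

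**Figure D1:**
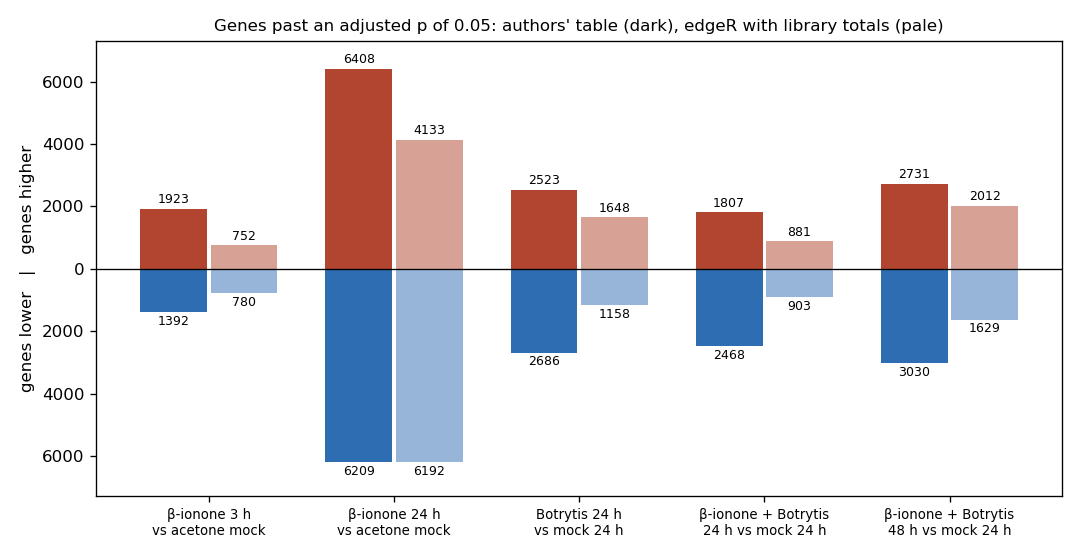
Genes higher and lower than in the control, past an adjusted p of 0.05. Dark bars count the authors' tables; pale bars count edgeR on the same genes scaled by library totals.

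Against the acetone mock, leaves after 3 h of β-ionone were higher in defence, jasmonate, ethylene and detoxification genes and lower in genes of aliphatic glucosinolate synthesis. This mock has identical counts under its 3 h and 24 h labels, so its time of harvest is unknown. How much of the 3 h change comes from the mock rather than from β-ionone is not known. 17 members of the immune list of 40 genes were higher and 0 lower (Fisher's exact test, adjusted p = 0.000967). Among them were the transcription factors WRKY22 (AT4G01250, 2255 ± 329 against 444 ± 57.2, log2 2.34, SE 0.20, authors' adjusted p 1.51e-32) and WRKY18 (AT4G31800, 5059 ± 105 against 1187 ± 304, log2 2.09, SE 0.21, authors' adjusted p 4.47e-26). The ubiquitin ligase gene PUB22 (AT3G52450) rose from 89.6 ± 45.0 to 808 ± 226 (3.17, SE 0.40, authors' adjusted p 4.74e-18). 17 of 38 detoxification genes were higher and 0 lower (exact test, adjusted p = 0.000967). They include the glucosyltransferase UGT73B3 (AT4G34131, 153 ± 24.0 against 17.7 ± 6.87, log2 3.11, SE 0.49) and the efflux carrier DTX1 (AT2G04040, 2.80).

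Of the jasmonate list of 30, 10 members were higher and 0 lower at 3 h (exact test, adjusted p = 0.0321). CYP94C1 (AT2G27690), which oxidises the active hormone conjugate, went from 131 ± 48.9 to 1278 ± 98.3 (3.29, SE 0.28), and ST2A (AT5G07010), which sulfates hydroxyjasmonate, from 82.7 ± 66.3 to 1769 ± 1235 (4.42, SE 1.12). Of 28 ethylene genes, 12 were higher and 1 lower (exact test, adjusted p = 0.0408). The ACC synthase gene ACS8 (AT4G37770) reached 2213 ± 271 from 242 ± 101 (3.19, SE 0.31, authors' adjusted p 2.73e-30). With a 2-fold minimum, neither hormone list passed (6/0 and 9/0 members higher/lower, exact test, adjusted p = 0.152 and 0.0602). Neither did the aliphatic glucosinolates, for which 6 of 20 genes were lower and 0 higher at any size (exact test, adjusted p = 0.0321, 0.0602 with the 2-fold minimum). Their regulator MYB28 (AT5G61420) fell from 2321 ± 721 to 803 ± 213 (−1.53, SE 0.28, authors' adjusted p 1.6e-08) and the sulfotransferase SOT18 (AT1G74090) from 679 ± 229 to 266 ± 66.9 (−1.35).

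The largest rises at 3 h were in ESC (AT1G20900), an AT-hook protein gene (226 ± 30.7 against 0, at least 233-fold), RAP2.6 (AT1G43160, 242 ± 146 against 6.77 ± 10.9, log2 5.16, SE 1.63), HB4 (AT2G44910, 195 ± 39.2 against 8.79 ± 2.80, log2 4.47, SE 0.51) and ST2A. They were followed by IOS1 (AT1G51800, 574 ± 357 against 29.9 ± 20.3, log2 4.26) and ZAT7 (AT3G46090, 342 ± 148 against 20.7 ± 12.3, log2 4.05). The largest falls were in the expansin gene EXPA8 (AT2G40610, 355 ± 148 against 3387 ± 1384, log2 −3.25, SE 0.34), UMAMIT46 (AT3G28070, −3.06), AGP3 (AT4G40090, −2.83), bHLH071 (AT5G46690, −2.70), CYCP4;1 (AT2G44740, −2.45) and RGF9 (AT5G64770, −2.40). The touch-responsive TCH4 (AT5G57560) rose (35914 ± 1919 against 7873 ± 3196, log2 2.19), as did the shade-responsive HB-2 (AT4G16780, 4986 ± 1373 against 808 ± 139, log2 2.62). 4CL1 (AT1G51680) of lignin synthesis fell from 2163 ± 373 to 412 ± 104 (−2.39). At 3 h 1923 genes were higher and 1392 lower, with non-overlapping groups in 3112 (93.9%), a share that follows in part from choosing genes on these same libraries. edgeR on the same genes kept 1629 (1048 higher, 581 lower, 752 and 780 scaled by library totals, 464 and 1160 scaled by TMM). Its count fell to 631 and 907 without β-ionone replicates 1 and 3, and to 657 and 376 without mock replicates 1 and 2.

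At 24 h of β-ionone, leaves had lost photosynthesis transcripts and gained those of senescence, abscisic acid response and detoxification. A second 24 h mock, without β-ionone, stood close to the treated leaves for most of these genes. 43 of 53 photosynthesis genes were lower and 2 higher (exact test, adjusted p = 3.84e-10). NPQ4 (AT1G44575), needed for photoprotective quenching, fell from 34994 ± 6358 to 1304 ± 112 (−4.75, SE 0.15). The antenna gene CAB3 (AT1G29910) fell from 373179 ± 45895 to 5497 ± 659 (−6.09, SE 0.14), and the chloroplast NDH subunit genes PnsL3 (AT3G01440, −6.20) and PnsB1 (AT1G15980, −6.15) fell as far. The 24 h mock was also low in this list, with medians on the scale of log2(FPKM + 1), used wherever the mocks are set side by side, of −1.82 against the acetone mock for that group and −2.02 for β-ionone over the 41 members that an infection table also holds. Of the senescence list of 14, 12 genes were higher and 0 lower (exact test, adjusted p = 0.00303). The transcription factor NAC3 (AT3G15500) reached 5059 ± 564 from 147 ± 40.7 (5.11), the chlorophyll-breakdown enzyme gene PPH (AT5G13800) 15102 ± 419.8 from 1682 ± 143 (3.17, SE 0.12), and XTH24 (AT4G30270) 159619 ± 16803 from 3935 ± 1146 (5.34, SE 0.20). Senescence medians over the 7 members that an infection table also holds were 3.28 for β-ionone and 2.79 for the 24 h mock.

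Of 29 abscisic acid genes, 20 were higher and 4 lower (exact test, adjusted p = 0.00725). HB-12 (AT3G61890) reached 10290.1 ± 1425 from 277 ± 38.6 (5.21, SE 0.16, authors' adjusted p 2.16e-226), ABF3 (AT4G34000) 4789 ± 1005 from 111 ± 31.0 (5.43, SE 0.22) and the phosphatase gene HAB1 (AT1G72770) 4618 ± 444 from 331 ± 39.9 (3.80). Detoxification had 23 of 38 higher and 2 lower (exact test, adjusted p = 0.000231), with CYP81D11 (AT3G28740) at 4598 ± 3482 against 4.09 ± 4.47 (10.13) and GSTU16 (AT1G59700) at 4543 ± 217 against 258 ± 78.2 (4.14). Jasmonate had 15 of 30 higher and 1 lower (exact test, adjusted p = 0.00303), with the repressor genes TIFY7 (AT1G70700) at 8822 ± 1839 against 1214 ± 298 (2.86, SE 0.20) and JAZ7 (AT2G34600) at 714 ± 242 against 26.4 ± 20.2 (4.75). Over the 15, 16 and 8 members of these 3 lists that an infection table also holds, medians were 1.46, 1.02 and 0.89 for β-ionone and 1.21, 0.90 and 0.70 for the 24 h mock. The clock list had 14 of 22 higher and 3 lower (exact test, adjusted p = 0.0493), among them PRR9 (AT2G46790, 5.68). Over the 9 of its members that an infection table also holds, medians were 0.21 with β-ionone and 1.21 in the 24 h mock. These members are mixed, with 5 higher and 4 lower in the 24 h mock than in the acetone mock by edgeR. Gene by gene, the median between β-ionone and the 24 h mock was only 0.12, and all 9 had the same direction in both groups. The gap between the 2 medians is thus no shift of the list. With a 2-fold minimum, ethylene (9/1, exact test, adjusted p = 0.0251), aliphatic glucosinolate (1/10, 0.028) and touch genes (6/0, 0.028) passed as well. At any size they did not (11/2, 2/10 and 6/2, exact test, adjusted p = 0.065, 0.065 and 0.512).

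Among the dioxygenases that can release β-ionone from carotenoids, NCED4 and CCD1 were higher at 24 h. NCED4 (AT4G19170, CCD4) stood at 4652 ± 1071 against 1886 ± 395 (2.47-fold, SE 0.20 in log2, authors' adjusted p 2e-10) and CCD1 (AT3G63520) at 21146 ± 440.4 against 12275 ± 682 (0.78, SE 0.11). At 3 h, against the same control counts, NCED4 was instead lower (log2 −0.92, authors' adjusted p 0.00969). Upstream, the first carotenoid enzyme gene PSY (AT5G17230) fell at 24 h from 6937 ± 140.0 to 1295 ± 97.6 (−2.42, SE 0.12). In FPKM, CCD1 was 204 ± 2.64 with β-ionone, 181 ± 75.1 in the 24 h mock and 159 ± 17.2 in the acetone mock. The largest rises of all over the acetone mock were in the β-glucosidase gene DIN2 (AT3G60140, 14548 ± 1939 against 0, at least 16331-fold, though high in the 24 h mock too), CYP71B14 (AT5G25180, at least 1715-fold) and M10 (AT2G41280, at least 1220.4-fold). Next came the peroxidase gene TPX2 (AT1G65970, 186292 ± 44098 against 32.7 ± 11.8, log2 12.48, SE 0.24), FLP1 (AT4G31380, at least 657-fold) and the glyoxalase gene GLYI7 (AT1G80160, 45693 ± 1929.6 against 15.6 ± 6.15, log2 11.53, SE 0.24). The largest falls, beside PnsL3, PnsB1 and CAB3, were in MES18 (AT5G58310, 0 against 326 ± 135, at least 298-fold), GIS (AT3G58070, −6.95) and the germin-like gene GER3 (AT5G20630, −6.52). 6408 genes were higher and 6209 lower, 53.6% of the 23536 the authors tested, with non-overlapping groups in 12273 (97.3%). edgeR kept 12307 (6266 higher, 6041 lower). Scaled by library totals it called 4133 higher and 6192 lower.

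For the genes that can be compared, the 24 h result depends on which mock is used. The labels give both mocks the same acetone and detergent. The acetone mocks labelled 3 h and 24 h hold identical counts, in 2540 of 2540 genes for each of 3 replicates, and so count as 1 set of libraries whose time is unknown. GLYI7 stood at 706 ± 26.0 FPKM with β-ionone, 338 ± 136 in the 24 h mock and 0.320 ± 0.116 in the acetone mock. In the same order CAB3 stood at 83.6 ± 9.40, 289 ± 48.9 and 7597 ± 502. HB-2 stood at 338 ± 47.9, 354 ± 70.0 and 14.0 ± 2.90, and NAC3 at 61.1 ± 6.35, 46.9 ± 16.3 and 2.36 ± 0.581. The change from acetone mock to 24 h mock followed the change to β-ionone over 4144 genes listed in the 24 h table and in an infection table. The slope was 0.893 (r = 0.970), with 93.3% of the genes in the same direction. Its bootstrap 95% interval, 0.885–0.901, resamples genes and leaves out the spread between libraries. Without 1 library of the 24 h mock the slope ran from 0.877 to 0.907. Both changes use the acetone mock. With separate acetone mock libraries for each the slope was 0.842–0.893, and with an acetone mock library in place of the 24 h mock it was 0.00209–0.0574 (r of 0.227 at most). edgeR in 1 fit called 3365 of 4633 genes different between the 2 mocks (1225 higher, 2140 lower in the 24 h mock, and 1806 and 1617 scaled by TMM). Between β-ionone at 24 h and the 24 h mock it called 1, CAB3 (lower, edgeR adjusted p = 0.012, 597 genes before adjustment). The 24 h mock libraries differed widely (SD of 1.01–1.26 log2 units), so this low count does not by itself show the groups to be alike. For infected groups against this mock, edgeR recovered 0–3% of simulated 2-fold and 32–55% of 4-fold changes. The pair of β-ionone and this mock was not simulated. The genes compared are the 4663 of the 12617 that an infection table lists as well, and nothing was tested for the others.

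**Figure D2:**
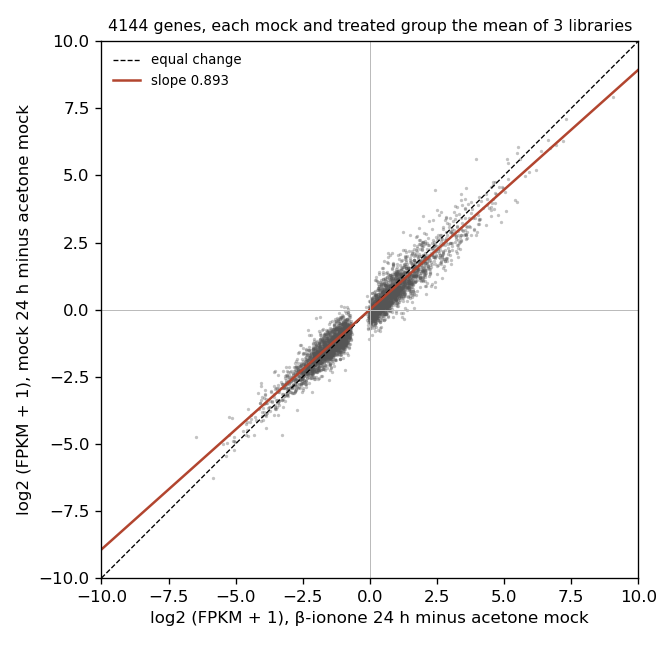
Change of 4144 genes from the acetone mock to 24 h of β-ionone and to the 24 h mock, in log2(FPKM + 1). The solid line has slope 0.893; the dashed line marks equality.

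From 3 h to 24 h of β-ionone, single genes moved far in both directions. WRKY18 (−3.88), PP2-A5 (AT1G65390, 2.59 ± 1.77 at 24 h against 768 ± 176 at 3 h, log2 −8.16) and CYP94C1 (55.1 ± 17.0 against 1173 ± 90.2, log2 −4.41) fell. So did the salicylate genes WRKY70 (AT3G56400, 137 ± 61.0 against 1905 ± 180, log2 −3.80) and EDS16 (AT1G74710, 32.8 ± 19.0 against 683 ± 117, log2 −4.37), all past edgeR's adjusted p of 0.05. CAB2 (AT1G29920) fell from 266370 ± 18378 to 4474 ± 632 (−5.90) and the sulfate reductase gene APR3 (AT4G21990) from 2321 ± 698 to 52.5 ± 31.4 (−5.46). Rises were led by TPX2 (186292 ± 44098 against 161 ± 38.4, log2 10.17), GLYI7 (8.61), LTP2 (AT2G38530, 6.19), WRKY45 (AT3G01970, 6287 ± 459.7 against 92.7 ± 89.5, log2 6.09), MES16 (AT4G16690, 5.99) and the methionine lyase gene MGL (AT1G64660, 5.65). CYP81D11 (5.29) and HB-12 (4.18) also rose. edgeR called 1684 of 2540 genes listed at both times different (932 higher, 752 lower at 24 h, 827 and 889 scaled by TMM, 786 and 985 by library totals), and 394 of the 2540 changed direction between the times. No list passed for direction (photosynthesis 0/4, exact test, adjusted p = 0.673). With identical mock counts at both times, the passage of a day in untreated leaves is not removed from this difference.

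Infection with Botrytis for 24 h raised nearly every defence pathway tested and lowered every listed auxin and photosynthesis gene. 29 of 40 immune genes were higher and 1 lower (exact test, adjusted p = 9.61e-08), and 18 of 27 salicylate genes higher and 0 lower (9.18e-06). Jasmonate genes had 13 of 30 higher and 0 lower (exact test, adjusted p = 0.000291) and ethylene genes 11 of 28 higher and 1 lower (0.00641). WRKY33 (AT2G38470), required for resistance to this fungus, rose from 1423 ± 568 to 10840.1 ± 719 (2.93, SE 0.37, authors' adjusted p 9.83e-13) and WRKY70 from 199.9 ± 57.0 to 4429.8 ± 546 (4.47, SE 0.31). ORA59 (AT1G06160), where jasmonate and ethylene signals meet, rose from 86.9 ± 28.4 to 936 ± 140.5 (3.44, SE 0.33), MYC2 (AT1G32640) from 1259 ± 162 to 2565 ± 253 (1.03, SE 0.21) and the oxylipin cyclase gene AOC1 (AT3G25760) from 599 ± 443 to 4374 ± 1192 (2.87). The receptor kinase gene FRK1 (AT2G19190) rose from 149.8 ± 21.8 to 793 ± 141 (2.40, SE 0.27).

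Genes on routes from tryptophan rose together: 10 of 12 indole glucosinolate genes (exact test, adjusted p = 0.00194) and 12 of 23 camalexin and tryptophan genes (0.000517) were higher and 0 lower. Their regulator MYB51 (AT1G18570) went from 575 ± 298 to 5709 ± 1313 (3.31, SE 0.44), CYP83B1 (AT4G31500) from 634 ± 541 to 11650.2 ± 1601 (SE 0.59 in log2), the indole-modifying CYP81F2 (AT5G57220) from 375 ± 242 to 5088 ± 1448 (3.76, SE 0.51) and the transporter gene PEN3 (AT1G59870) from 6249.8 ± 1856 to 35250.1 ± 3918 (2.50). The camalexin genes PAD3 and CYP71A13 were not listed, so a rise of the last steps to camalexin is not shown. Detoxification had 20 of 38 higher and 0 lower (exact test, adjusted p = 2.67e-06), with OPR1 (AT1G76680) at 4719 ± 521 against 282 ± 163 (4.06). Lignin-branch genes had 10 of 16 higher and 1 lower and heat genes 10 of 23 higher and 1 lower (exact test, adjusted p = 0.01 for each). FAH1 (AT4G36220) reached 6182 ± 646 from 665 ± 396 (3.22), CAD5 (AT4G34230) 5056 ± 975 from 773 ± 384 (2.71) and HSP70 (AT3G12580) 2116 ± 489 from 126 ± 132 (4.07). The strigolactone dioxygenase genes rose steeply, CCD8 (AT4G32810) from 50.1 ± 10.2 to 2157 ± 1132 (5.42, SE 0.49, authors' adjusted p 4.83e-26) and CCD7 (AT2G44990) from 89.1 ± 70.8 to 1643 ± 463 (SE 0.62 in log2). CCD1 and NCED4 were not listed, and carotenoid genes as a list did not pass (5/1 of 26, exact test, adjusted p = 0.193).

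All 30 listed auxin and cell-expansion genes of 32 were lower in infected leaves (exact test, adjusted p = 2.75e-08), and so were all 42 listed photosynthesis genes of 53 (1.67e-11). IAA29 (AT4G32280) fell from 4931 ± 595 to 138 ± 57.7 (−5.16, SE 0.37), IAA19 (AT3G15540) from 846 ± 205 to 31.6 ± 10.1 (−4.73) and IAA1 (AT4G14560) from 1423 ± 534 to 40.8 ± 14.2 (−5.12). CAB1 (AT1G29930) fell from 1468330 ± 235202 to 107547 ± 32191 (−3.77, SE 0.31) and PSBP-1 (AT1G06680) of photosystem II from 132588 ± 8132 to 33424 ± 2824 (−1.99, SE 0.17). Abscisic acid genes were divided, 7 higher and 7 lower, with the cold and drought markers LTI78 (AT5G52310, RD29A, 524 ± 85.2 against 4121 ± 1230.0, log2 −2.97, SE 0.33) and COR15B (AT2G42530, 15.7 ± 5.10 against 509 ± 194, log2 −5.00) among the falls. The largest rises were in WRKY54 (AT2G40750, 316 ± 119 against 0, at least 282-fold), ANK (AT5G54610, at least 227-fold) and the expansin-like EXLB1 (AT4G17030, 291 ± 65.5 against 0.989 ± 1.71, log2 8.04). Next came the nicotianamine synthase gene NAS3 (AT1G09240, 3359 ± 1441 against 27.7 ± 25.9, log2 6.92, SE 0.79), the subtilase gene SBT3.3 (AT1G32960, 6.42) and the peroxidase gene PRXCA (AT3G49110, 6.07). The largest falls were in the ACC synthase gene ACS5 (AT5G65800, 237 ± 72.9 in the control, at least 279-fold), ADS1 (AT1G06080, 13.4 ± 18.5 against 3221 ± 978, log2 −7.91), CAB3 (−6.14), P1R3 (AT3G29370, −6.13), XYP2 (AT2G13820, −6.00) and KDR (AT1G26945, −5.84).

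2523 genes were higher and 2686 lower after infection alone, 23.7% of the 22013 tested, with non-overlapping groups in 5123 (98.3%). DESeq2 kept 5069 and edgeR 3139 (1590 higher, 1549 lower, 1648 and 1158 scaled by library totals). The libraries of the 24 h mock, against which all 3 infected groups were compared, differed from one another with an SD of 1.01–1.26 log2 units, against 0.435–0.792 in the other groups. edgeR's count fell to 905, 283 and 609 without infected replicate 1, 2 or 3. This mock is titled 24 h but coded 0 h in its sample names, so the passage of a day is not ruled out as part of any infected comparison.

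When β-ionone came before the fungus, leaves at 24 h raised salicylate, immune, indole glucosinolate, detoxification and lignin-branch genes and lowered auxin and photosynthesis genes. Salicylate genes had 16 of 27 higher and 0 lower (exact test, adjusted p = 5.5e-06), and immune genes 21 of 40 and 0 (1.44e-07). Indole glucosinolate genes had 8 of 12 and 0 (exact test, adjusted p = 0.0037), detoxification genes 14 of 38 and 1 (0.000226) and lignin-branch genes 7 of 16 and 0 (0.00753). WRKY70 rose from 193 ± 55.5 to 2736 ± 297 (3.82, SE 0.29, authors' adjusted p 1.57e-31), WRKY33 from 1370.1 ± 545 to 5457 ± 269 (1.99, SE 0.36), FRK1 from 144 ± 20.6 to 1365 ± 295 (3.24, SE 0.26) and ORA59 from 83.6 ± 27.2 to 544 ± 32.7 (2.71, SE 0.30). Jasmonate (4/0), camalexin (4/0) and ethylene genes (9/6) did not pass for direction (exact test, adjusted p = 0.0779, 0.0779 and 0.329). All 30 listed auxin genes and all 40 listed photosynthesis genes were lower (exact test, adjusted p = 9.24e-07 and 6.03e-09), with IAA29 at 120.3 ± 37.4 against 4748 ± 582 (−5.30, SE 0.29) and the antenna gene LHCB2.3 (AT3G27690) at 1123 ± 82.9 against 6971 ± 1782 (−2.63, SE 0.26).

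Among the largest rises here were ANK (211 ± 84.8 against 0, at least 196-fold), the receptor kinase gene RLK1 (AT5G60900, 329.8 ± 85.9 against 7.28 ± 11.8, log2 5.46) and the chitinase gene CHIA (AT5G24090, 219 ± 66.7 against 5.06 ± 8.76, log2 5.39). Others were PCC1 (AT3G22231, 614 ± 405 against 16.1 ± 12.2, log2 5.29), LURP1 (AT2G14560, 1041 ± 675 against 30.3 ± 18.6, log2 5.12, SE 0.65) and NAS3 (5.04). The largest falls were in the cell-surface protein gene FLA1 (AT5G55730, 1.16 ± 1.01 against 249 ± 136, log2 −7.72), ADS1 (−6.64), ACS5 (−5.94), P1R3 (−5.76), the nitrate reductase gene NIA1 (AT1G77760, 19.9 ± 9.26 against 1005 ± 1339, log2 −5.67) and PHE1 (AT1G65330, −5.62). 1807 genes were higher and 2468 lower, 19.6% of 21839 tested. Scaled by TMM, edgeR called 1457 higher and 763 lower, and with the authors' scaling 803 and 1090. Without 1 treated library edgeR's 1893 became 0, 0 or 41 (3631 and 3672 genes before adjustment for the first pair). Without mock replicate 2 or 3 it became 3133 or 1166.

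Side by side, infection after β-ionone moved the shared genes the same way as infection alone, but less far. All 3458 genes listed in both tables had the same direction, and 2548 of them (73.7%) changed less in the combination, with a median size of 1.66 against 1.91 in log2. Fitting all groups jointly, edgeR called 0 of 3411 genes different (513 before adjustment). Without mock replicate 1, 2 or 3, in neither compared group, it called 122, 293 or 66. On all libraries DESeq2 called 283 (81 higher, 202 lower) and limma on FPKM 68. In simulated data for this comparison 18.0% of DESeq2's calls were of unchanged genes, against 6.59% of edgeR's. edgeR on the compared groups alone, tried after the values were seen, called 131 higher and 424 lower in the combination, and the genes named next come from that fit. WRKY33 was 5457 ± 269 in the combination and 10435 ± 693 after infection alone (−0.94, edgeR adjusted p = 0.00042), MYB51 2098 ± 229 and 5496 ± 1264 (−1.39), and CYP81F2 1644 ± 204 and 4898 ± 1394 (−1.58). The ACC synthase gene ACS6 (AT4G11280) was 1135 ± 101 and 3587 ± 522 (−1.66), and the pathogenesis-related PR4 (AT3G04720) 8898 ± 1258 and 28187 ± 5737 (−1.66, edgeR adjusted p = 0.000206). The aldehyde oxidase gene AO1 (AT5G20960) was 553 ± 38.2 and 2501 ± 303 (−2.18, edgeR adjusted p = 3.56e-05). FRK1, at 1365 ± 295 and 763 ± 136 (0.84, edgeR adjusted p = 0.00906), was the only immune gene this fit called higher, and LTI78 kept 921 ± 94.5 against 504 ± 82.1 (0.87).

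By list, 7 of 8 tested indole glucosinolate genes, 11 of 14 detoxification genes, 9 of 20 immune genes and 6 of 9 ethylene genes were lower in the combination in the fit of the groups alone. None of these counts passed for direction against the other genes, as 424 of the 555 called were lower (exact test, adjusted p = 0.755, 0.400, 1 and 0.917). Auxin genes did pass in the other direction, with 4 of 25 higher and 0 lower (exact test, adjusted p = 0.0479), among them the repressor SHY2 (AT1G04240, 1251 ± 145 against 799.7 ± 76.6, log2 0.64). Genes listed in only 1 of the tables, 817 and 1751, are outside this comparison.

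**Figure D3:**
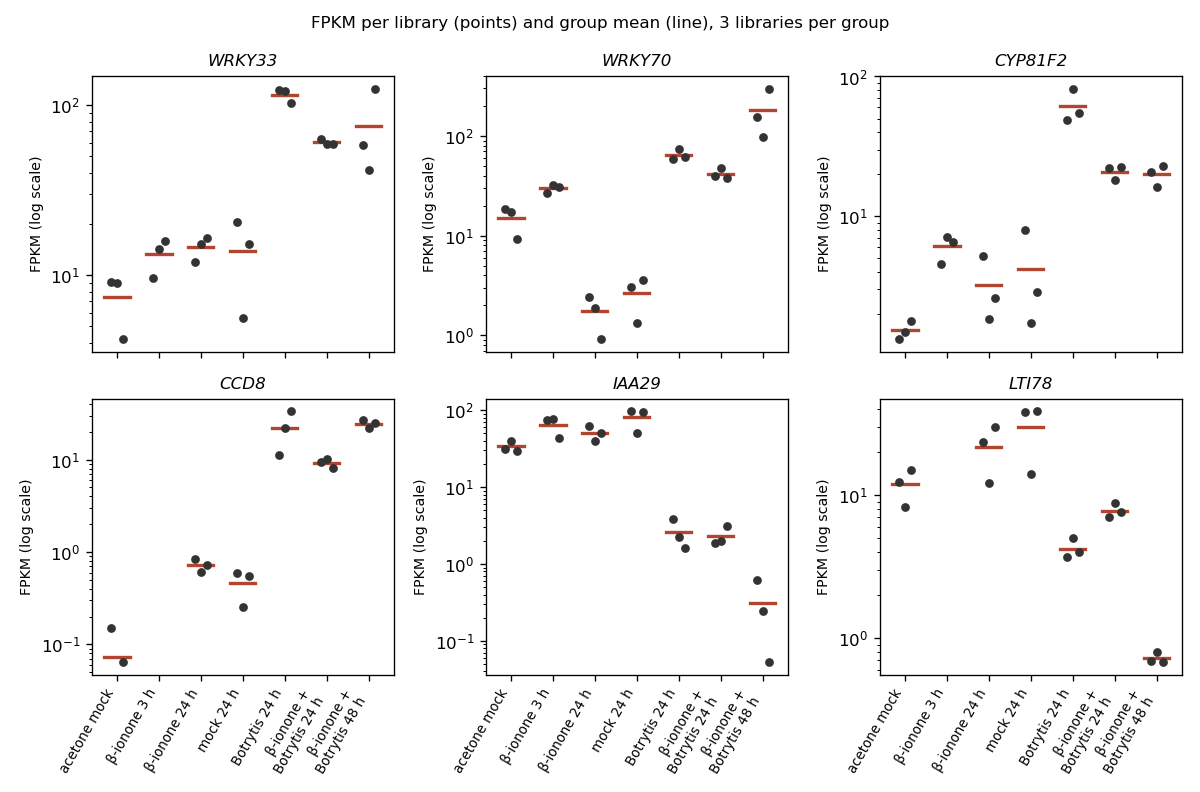
FPKM per library of 6 genes, with group means, on a log axis. A library at 0 (1 acetone mock library for CCD8) and a group in which the gene is not listed (3 h of β-ionone for CCD8 and LTI78) are not drawn.

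At 48 h after infection, β-ionone-treated leaves carried the most changed salicylate and photosynthesis genes of the series. Their control is the 24 h mock, as no 48 h mock is among the labels. 20 of 27 salicylate genes were higher and 0 lower (exact test, adjusted p = 1.74e-06), and WRKY70 rose from 188 ± 54.3 to 11379 ± 5572 (5.92, SE 0.46, authors' adjusted p 4.18e-35). LURP1, a defence gene downstream of salicylate, rose from 29.5 ± 18.0 to 6005 ± 740.5 (7.70, SE 0.48). Immune genes had 26 of 40 higher and 1 lower (exact test, adjusted p = 5.81e-07) and camalexin and tryptophan genes 10 of 23 and 0 (0.00208). Indole glucosinolate genes had 8 of 12 and 0 (exact test, adjusted p = 0.00797) and detoxification genes 18 of 38 and 1 (8.69e-05). SYP122 (AT3G52400) reached 5581 ± 601 from 663 ± 184 (3.07), CYP83B1 6442 ± 459.9 from 593 ± 505 (3.44) and GSTF3 (AT2G02930) 3160.3 ± 549 from 142 ± 102 (4.47). Heat (10/1 of 23), lignin-branch (8/1 of 16) and jasmonate genes (8/1 of 30) passed too (exact test, adjusted p = 0.0121, 0.0358 and 0.0358), as did senescence genes (5/0 of 14, 0.0478). Jasmonate and senescence did not with a 2-fold minimum (exact test, adjusted p = 0.101 and 0.171). PDF1.2b (AT2G26020), a defensin gene with near-identical relatives, was 351 ± 172 against 13.6 ± 8.06 (4.67).

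All 49 listed photosynthesis genes of 53 and all 30 listed auxin genes of 32 were lower at 48 h (exact test, adjusted p = 5.16e-13 and 4.56e-08). CAB1 fell from 1375530 ± 216540 to 33705 ± 7675 (−5.35, SE 0.28) and IAA29 from 4622 ± 575 to 15.4 ± 13.9 (−8.23, SE 0.68, authors' adjusted p 1.53e-32). LTI78 fell from 3864 ± 1165 to 84.2 ± 16.0 (−5.52, SE 0.36), the flavonoid entry gene TT4 (AT5G13930) from 1009 ± 318 to 50.5 ± 14.5 (−4.33) and the wax gene CER1 (AT1G02205) from 288 ± 138 to 4.00 ± 4.35 (−6.12, SE 0.78). CCD1 fell from 17109 ± 4378 to 8332 ± 858 (−1.04, SE 0.29, authors' adjusted p 0.00499), while CCD8 was higher (2178 ± 134 against 47.0 ± 9.65, log2 5.52, SE 0.27). The largest rises were in WRKY54 (1092 ± 565 against 0, at least 1039-fold), ANK (at least 803-fold), EXLB1 (8.68), PCR1 (AT1G14880, 1439 ± 927 against 4.76 ± 4.13, log2 8.27), LURP1 and NAS3 (6.98). The largest falls were in ADS1 (0 against 3019 ± 921, at least 3289-fold), MIR169m (AT3G26818, at least 268-fold), ACS5 (at least 241-fold), IAA29, PHE1 (−8.11) and RCI2B (AT3G05890, 5.46 ± 4.52 against 1305 ± 975, log2 −7.87). 2731 genes were higher and 3030 lower, 25.5% of 22586 tested. edgeR kept 4059 (1917 higher, 2142 lower, and 2012 and 1629 scaled by library totals). Without treated replicate 1, 2 or 3 edgeR's count was 1331, 1964 or 1727.

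Between 24 h and 48 h of the combined treatment, salicylate genes climbed further and photosynthesis genes fell further. 5 of 15 tested salicylate genes were higher at 48 h and 0 lower (exact test, adjusted p = 0.0238). WRKY70 went from 2663 ± 289 to 11379 ± 5572 (edgeR adjusted p = 0.0065), WRKY54 from 189 ± 23.1 to 1092 ± 565 (2.53) and the salicylate synthesis gene EDS16 from 522 ± 91.0 to 3357 ± 2741 (2.69, edgeR adjusted p = 0.0384). 4 of 18 immune genes were higher and 0 lower (exact test, adjusted p = 0.0466), among them WRKY18 (1.55) and SYP122 (1.00). 15 of 40 photosynthesis genes were lower and 0 higher (exact test, adjusted p = 0.0191), with CAB1 going from 146527 ± 25691 to 33705 ± 7675 (−2.12, edgeR adjusted p = 0.0036) and PSBP-1 from 37553 ± 4582 to 14676 ± 3474 (−1.36). ORA59 (1.23) and CCD8 (2178 ± 134 against 823 ± 84.5) rose. By contrast LTI78 (897 ± 92.0 to 84.2 ± 16.0, log2 −3.41), IAA29 (−2.93), TT4 (−2.37), CER1 (−4.78) and the glucomannan synthase gene ATCSLA09 (AT5G03760, 206 ± 94.2 to 10.5 ± 1.45, log2 −4.29) fell. edgeR called 544 of 3246 genes listed at both times different (188 higher, 356 lower at 48 h, limma on FPKM 234 and 254). Without a single library this ranged from 159 to 839, with 193 and 246 without 48 h replicates 1 and 3, and 277, 200 and 159 without 24 h replicates 1, 2 and 3.

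**Figure D4:**
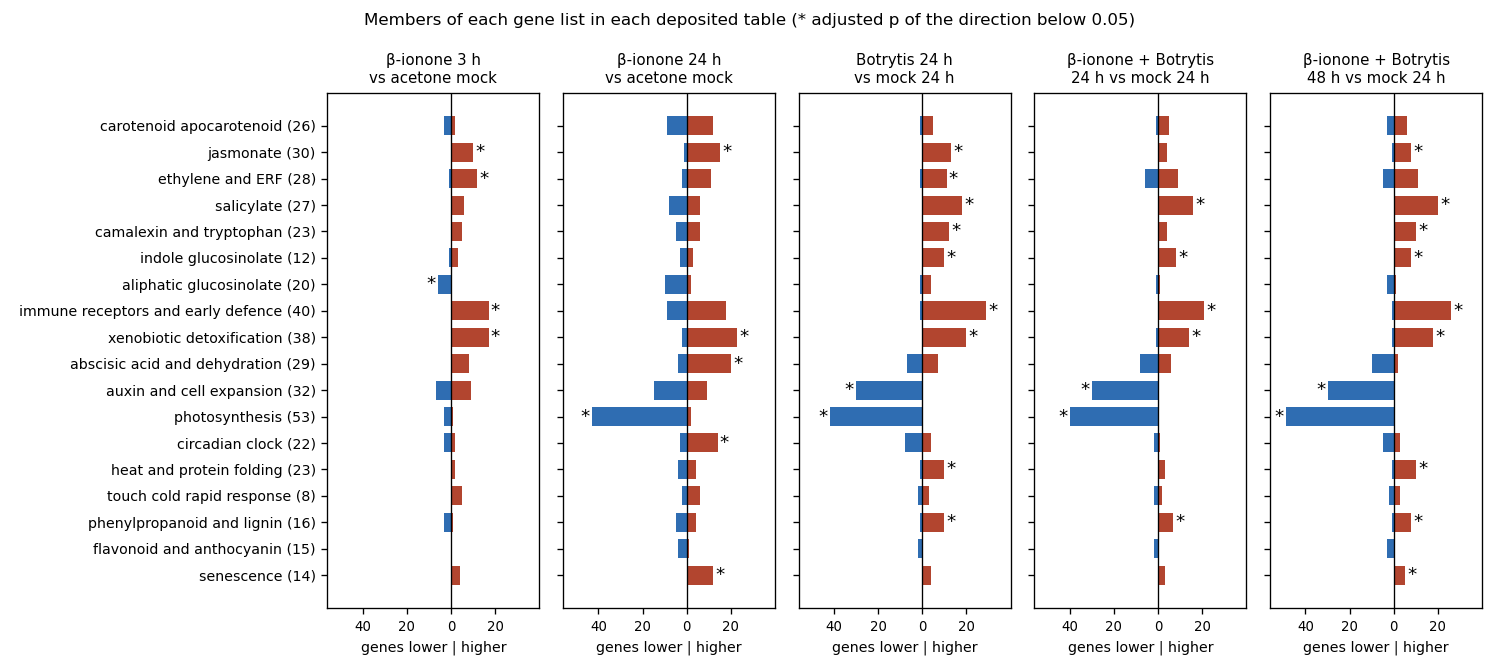
Members of the 18 pathway lists higher (right) or lower (left) in each of the 5 tables. A star marks an adjusted p for direction below 0.05.

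The 3 infected groups share a core. 2940 genes were listed in all 3 tables, 1280 higher and 1660 lower in each and 0 mixed. WRKY33, WRKY70, MYB51, CYP83B1 and CCD8 are among the rises and IAA29, CAB1, LTI78 and ADS1 among the falls. Infection alone and the combination at 24 h shared 1485 higher and 1973 lower genes, where independent tables of these sizes would share 209 and 304. Part of such an excess can come from the controls the tables share. Simulated tables with no effect and shared controls had at most 0 shared calls. Their r of 0.505 was taken without choosing genes by p-value. It is therefore no baseline for the r = 0.967 of the listed genes here. The 3 h and 24 h tables of β-ionone shared 2540 genes, 2146 (84.5%) in the same direction (1239 higher and 907 lower against 653 and 458 if independent). They share every control library. Simulated tables with no effect had r = 0.504 and 66.6% of genes in the same direction, again without choosing genes by p-value. These values are no baseline for the r = 0.709 and 84.5% here, so the part due to shared controls is unknown. Tables without a shared library also overlapped. Of 3325 genes in both the 24 h β-ionone table and the table of infection alone, 2045 (61.5%) had the same direction and 1280 the opposite (Fisher's exact p = 3.90e-40, odds ratio 2.56). That test treats genes as independent and leaves out the spread between libraries. The 24 h mock followed the β-ionone change with slope 0.893, so this overlap cannot be credited to β-ionone rather than to the difference between the mocks. The opposing genes include LTI78, above the acetone mock with β-ionone (1.29) and below the 24 h mock with infection, and WRKY70, the other way round. Each direction under β-ionone rests on the acetone mock; with β-ionone and in the 24 h mock LTI78 was 21.7 ± 8.87 and 30.02 ± 13.9 FPKM, and WRKY70 1.74 ± 0.771 and 2.62 ± 1.16.

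Of the flavonoid list and the cell-type lists at most 5 members were in any table. Flavonoid genes had 1/4 members higher/lower at 24 h of β-ionone, 0/2 after infection alone and 0/3 at 48 h of the combination, with none at 3 h. Of the cell-type lists, dividing-cell genes were only lower (0/3, 0/2, 0/2 and 0/1 of 4, in table order from 24 h of β-ionone), vascular genes 0/1, 0/1 and 0/2 of 4 after infection and epidermis and trichome genes 0/1, 0/1 and 0/3 of 6. Guard-cell genes (at most 1 each way of 4) and flower or bolting genes (1 of 3, in 1 table) barely appeared, and no cell-type list passed for direction. Of the named members, the guard-cell channel gene KAT1 (AT5G46240) rose at 3 h of β-ionone (1067 ± 32.5 against 453 ± 73.9, log2 1.24) and fell after infection alone (130.0 ± 27.6 against 489 ± 135, log2 −1.92). The cellulose synthase gene IRX1 (AT4G18780) fell at 48 h (−5.30, from 79.7 ± 5.23). Across 108 tests of 23 lists, 40 passed for direction, 32 of them towards higher; with a 2-fold minimum 38 passed, 35 of them the same.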

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

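The no-change value of the slope and the tests of transcript length and depth in the 24 h mock, of depth at 24 h of β-ionone, of depth and of change size in the combination, and all splits of samples were chosen only after the result was seen; the tests of clock genes, of the slope between the mocks, of length at 24 h and of spread were written before.

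For β-ionone, 12617 genes were listed at 24 h and 3315 at 3 h. Of the 2540 genes listed at both times, edgeR called 1684 different between the times. A control that differs from the treated leaves in sampling time or batch may account for most of the change in the 4633 genes that could be compared, of which the 2 mocks differed in 3365: the change from the acetone mock to the 24 h mock followed the β-ionone change with slope 0.893 (0.842–0.893 with separate acetone mock libraries, 0.0574 at most with an acetone mock library as the second mock), above the 0.75 set for that account. Depth (mean total of treated over control 1.09) and transcript length (bins explained −2.20% of the variance) were excluded as causes. Nothing was tested for the listed genes that no infection table holds, and how much of the 3 h response shares this origin stays open, since the same acetone mock serves there, where the 3 h change followed the 24 h change with slope 0.337.

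Replicate 2 of the 24 h mock stood apart, with SDs of 1.26 and 1.25 log2 units from replicates 1 and 3, which differed by 1.01; libraries of other groups differed by 0.435–0.792. Depth is excluded, its total being 1.03 times that of the others. A length trend could be part of it: removing length bins lowered the SD of its deviation from 1.15 to 0.951, within the limit of 0.998, though other groups reached 0.665 at most. Another time of day was not settled, with clock genes at percentile 92.3 among 10000 matched lists. Without this library edgeR's count for infection alone went from 3139 to 3564 for the combination at 24 h from 1893 to 3133 and at 48 h from 4059 to 4008.

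Fewer genes were listed for the combination at 24 h (4275) than for infection alone (5209). Over genes listed in both tables spread was not larger, the median SD within the combination being 0.718 times that of infection alone. Passing in both tables favours genes of small spread, so larger spread is not excluded for the other genes. Depth is excluded (mean total 0.916 times). Smaller changes could account for the lower count. Over genes listed in both tables their median size was 0.869 times that of infection alone, and 0.845–0.891 with any 1 library left out. This lies below the 0.9 set for that account, but the limit was set after the sizes were seen, so passing it restates them. The 817 and 1751 genes listed in only 1 of the tables, on which the difference in count rests, are not covered. Whether the β-ionone spray caused the smaller changes stays open, because the inoculations are not known to have been done together.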

How the results depend on the processing

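Only genes the authors called were open to refitting, so no setting could add a gene, gene-set tests such as camera and fry were not run, and a pseudocount was not varied because counts are deposited. Named genes kept their result in 4118 of 5107 gene and setting values (365 gene and comparison pairs, 208 genes), were weaker in 987 and reversed in 2: ABCG12 (AT1G51500) at 24 h of β-ionone, 0.30 in the authors' table, was −0.12 with limma on FPKM and −0.12 with library totals. Replicate numbers do not pair the groups (correlations of −0.151 to 0.404), so a block only removes degrees of freedom. Of other falls in count, the cause was not tested.

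β-Ionone at 3 h (3315): FDR 0.01 2078, 2-fold 1270, edgeR 1629, TMM 1624, no filter 1629, mean of 10 or more 1629, limma 1575, totals 1532, block 1035. Infection alone (5209): edgeR 3139, TMM 3209, no filter 3139, mean of 10 or more 2900, limma 3388, totals 2806, block 2198. Combination at 24 h (4275): FDR 0.01 2638, edgeR 1893, TMM 2220, no filter 1893, mean of 10 or more 1802, limma 2283, totals 1784, block 169. Combination at 48 h (5761): mean of 10 or more 3649, limma 3729, totals 3641, block 3652. β-Ionone at 24 h (12617) kept 4012 higher and 4401 lower with the 2-fold minimum. Over the 4633 genes that could be compared, edgeR called 3740 against the acetone mock and 1 with the 24 h mock as control. Libraries of the 24 h mock differed widely, so the second count can miss real differences.

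Combination against infection alone (0): DESeq2 283, limma 68, compared groups alone 555. 48 h against 24 h of the combination (544): DESeq2 873, FDR 0.01 132, compared groups alone 978. β-Ionone at 24 h against the 24 h mock (1): compared groups alone 0. Genes shared by the 3 infected groups (2940): FDR 0.01 1917. Genes with the same direction in β-ionone at 24 h and infection alone (2045): FDR 0.01 1281, 2-fold 1310.

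With each library left out edgeR's counts were 376–1405 for β-ionone at 3 h, 10929–11448 at 24 h, 283–3564 for infection alone, 0–3133 and 1331–4008 for the combination at 24 h and 48 h, 0–293 for combination against infection alone, 159–839 for 48 h against 24 h, 1595–1712 for β-ionone at 24 h against 3 h, 0–2 for β-ionone against the 24 h mock and 3004–3733 between the mocks.

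Of the 10 ways to split 6 libraries, 1 of 10, the real one, reached the real count in every comparison but 1. The 10 splits are too few for a share under 0.05, the smallest being 10%. In the 5 tables the genes were chosen by the authors' test on the real split. Fewer calls in the other splits of these tables were thus fixed in advance and give no support. Real and highest other counts were 1629 and 2, 12307 and 0, 3139 and 0, 1893 and 0, 4059 and 0 in table order, 555 and 0 for combination against infection alone, 978 and 0 for 48 h against 24 h, 1662 and 0 for β-ionone at 24 h against 3 h and 3062 and 0 between the mocks; for β-ionone at 24 h against the 24 h mock all 10 of 10 had 0.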

Other observations

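The list of dark and sugar genes and its test were chosen only after the result was seen, as was the comparison of the mocks by gene list.

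Genes that leaves use when starved of light or sugar rose with β-ionone, and rose in the 24 h mock too. All 11 listed members of the 16-gene dark and sugar list were higher at 3 h (Fisher's exact p = 0.00361) and 15 were higher with 1 lower at 24 h (exact p = 0.000527). The asparagine synthase gene ASN1 (AT3G47340) stood at 1978 ± 228 FPKM with β-ionone for 24 h, 1491 ± 415 in the 24 h mock and 83.2 ± 20.5 in the acetone mock; IVD (AT3G45300), of branched-chain amino acid breakdown, at 948 ± 38.2, 720.2 ± 163 and 30.1 ± 6.72; DIN2 at 123 ± 17.2, 96.8 ± 68.6 and 0. Medians of 7 members were 4.53 in β-ionone and 3.81 in the 24 h mock, in log2 over the acetone mock. After infection the list had 4/0, 4/0 and 2/2 members higher/lower. The list was drawn up because dark-induced genes had been seen to rise, so its 15 of 16 members restate that rise and do not test a response to darkness or sugar shortage. Whether such a state was shared by both groups stays open, and leaves of all groups harvested in the same hour would be the test.

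Some genes stood further from the 24 h mock with β-ionone than the bulk. CYP81D11, a P450 gene responsive to volatiles, was 53.5 ± 40.3 FPKM with β-ionone, 19.2 ± 11.2 in the 24 h mock and 0.0653 ± 0.0702 in the acetone mock, and the median over all 4144 genes was 0.26 log2 units in size between β-ionone and the 24 h mock against 1.19 between the mocks. Auxin genes had a median of −0.57 and touch genes of −0.59 between β-ionone and the 24 h mock (23 and 6 members), the furthest of the lists with more than 1 member compared. Only CAB3 passed there (edgeR adjusted p = 0.012), and 597 genes had an unadjusted p below 0.05.

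New leaves could test the following. β-Ionone may raise some defence genes only briefly: WRKY18, CYP94C1 and EDS16 were up at 3 h and lower at 24 h than at 3 h, although the jasmonate list still had 15/1 and the detoxification list 23/2 members higher/lower at 24 h, and edgeR called 1662 genes different between the times in the fit of the groups alone. A time course with a mock at each hour would show whether this decline follows β-ionone or the clock. β-Ionone before infection may delay or blunt defence genes: WRKY33, CYP81F2, ACS6 and WRKY70 were lower than after infection alone at 24 h in the fit of the groups alone (555 genes), and WRKY70 was higher at 48 h than at 24 h, with no group of infection alone at 48 h to set beside it. A smaller fungal load would give the same picture (change size 0.869 times that of infection alone), and fungal biomass in the same leaves, with infection alone at 48 h, would tell these apart.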
